A study of Homo sapiens with 12 samples.

How the data were processed

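RNA was measured by sequencing in 12 medulloblastoma xenografts passaged in the cerebellum of immunodeficient mice without culture, 1 library per xenograft, each from a different patient per the labels. Libraries were made with a stranded total RNA kit, per the labels' protocols. The deposited table holds whole numbers per gene, read here as estimated counts, made with HISAT2 2.1.0 and StringTie on the hg38 build per the submitters' processing notes. Those notes do not say whether the values are read counts or coverage turned into counts, which annotation release was used, how strands were handled, whether ribosomal RNA was removed or whether mouse reads were separated. The values are not scaled between libraries, since the totals differ from 28943508 to 114161338.

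Gene identifiers were matched to GENCODE release 29, which gave names, classes and positions. Of 58381 identifiers, 58261 matched by stable identifier and 56933 also by version, while 120 did not match. To keep personal detail out, 1275 genes were left out of everything but library totals: the X-inactivation transcript and its antisense gene, Y-linked genes, HLA, KIR, immunoglobulin and T cell receptor genes and genes with common germline deletions. The other 56986 genes included 15621 lncRNA and 19781 protein-coding genes.

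The labels put all libraries in 1 kind and give no subgroup per library, so relations across the 12 libraries were tested in place of groups. Counts were scaled with TMM library sizes in edgeR 4.0.16 (R 4.3.3) to CPM and log2 CPM with a prior count of 2. A gene counted as detected at 0.5 CPM in at least 3 libraries. Lists of known genes (21 lists, 205 genes, of which 204 were in the table and 179 detected) were fixed before the data were examined, as were the pairs, tests, alternatives and the rule for naming genes. The lists covered the WNT, sonic hedgehog, group 3 and group 4 subgroups, the hedgehog pathway, WNT targets, MYC targets, oncogenes, photoreceptor genes, proliferation, neuronal differentiation, the granule and unipolar brush lineages, NOTCH, TGF-beta and SMAD, imprinted genes, microglia, astrocytes, oligodendrocytes, endothelial cells with pericytes, and lncRNAs named in medulloblastoma work.

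Coherence of a list was the mean pairwise Spearman correlation of its detected members, set against 10000 random lists of the same size matched on mean log2 CPM in 20 bins (one-sided). Relations of 16 lncRNA and gene pairs and 12 list pairs were tested with Pearson's r and Spearman's rho and two-sided permutation p-values from 100000 permutations, or exact ones below 10 libraries. Each r was computed again without the 2 libraries farthest from the median of the first member. Where the largest gap between neighbouring values exceeded 0.4 of the range with at least 2 libraries on each side, the libraries were treated as separate clusters and tested only within clusters of at least 6. If both members of a pair fell into clusters, the libraries were split on the first member only. The variability of lncRNAs was compared with coding genes matched on mean log2 CPM in 20 bins, with 10000 draws of class labels. Genes related to MYC, MYCN, OTX2 and the proliferation list were found with edgeR's quasi-likelihood test, the log2 CPM or list mean as a covariate, genes kept by filterByExpr, and Benjamini-Hochberg adjustment at 0.05. This filter with 1 group keeps genes expressed in nearly all libraries. Slopes are log2 changes per unit of log2 of the covariate.

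Named genes were list members, members of the pairs, the 10 lncRNAs with the highest median CPM, the 10 lncRNA and 10 coding genes with the largest SD, and up to 5 lncRNA and 5 coding genes per covariate and direction by adjusted p, with ties taken in order of the unadjusted p. A few others are named with their choice stated.

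Alternatives were DESeq2 1.42.0 size factors, each library left out, detection at 1 CPM in 6 libraries, a prior count of 0.5, library sizes without mitochondrial genes and the 10 most abundant genes, no filter on low counts, DESeq2's Wald test and limma-trend (limma 3.58.1). Chosen after seeing the data were the 9 less deep libraries, the 7 libraries with fewer genes detected, that split as a term, and matching on the median or highest log2 CPM. The labels do not say whether this split is technical.

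The tests were tried on simulated data. With slopes of 0.25 and 0.5 planted in 100 genes each among 14688 for the MYCN comparison, 18% and 84% were recovered with 3 false calls. Of 300 unrelated pairs, 4.33% had a p under 0.05, and of 200 pairs with a true r of 0.85, 88.5% did. Analyses in Python 3.11.15 used numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.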

Results

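RNA was sequenced from 12 medulloblastoma xenografts, each grown in the cerebellum of immunodeficient mice from tumour cells of a different patient. All 12 libraries belong to 1 kind of sample in the labels. The series text speaks of different medulloblastoma subgroups, but no label gives the subgroup of a library, so no comparison between subgroups was made. The series concerns long noncoding RNAs (lncRNAs) in medulloblastoma. The questions addressed here are which lncRNAs were abundant or variable across the xenografts, which rose and fell with a neighbouring gene, which known gene programmes varied together, and which genes followed the oncogenes MYC, MYCN and OTX2. Libraries are numbered 1 to 12. The p-values cover the spread between these 12 libraries, 1 per xenograft, and subgroups that the labels do not give can produce relations of every kind reported here.

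The table gave counts for 58381 genes. Total counts ran from 28943508 in library 8 to 114161338 in library 5, and libraries 4, 5 and 6 were the deepest, each with at least 99503986. Genes with at least 1 count fell into 2 sets, and the set with more genes held 4 of the 5 least deep libraries while the set with fewer held the 5 deepest. Libraries 2 to 7 and 10 had 29057 to 31450 such genes, and libraries 1, 8, 9, 11 and 12 had 36958 to 44720. Small cytoplasmic and nuclear RNAs of the 7SL and 7SK families took 11.7% to 24.8% of the counts per library. Protein-coding genes took 64.7% to 79.3%, ribosomal protein genes 0.992% to 9.96%, mitochondrial genes 0.366% to 0.857% and lncRNA genes 1.33% to 4.07%. Pairs of libraries had Spearman correlations of 0.768 to 0.928 across 22225 genes, which are not independent replicates, and no pair differed by as little as sampling noise.

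**Figure D1:**
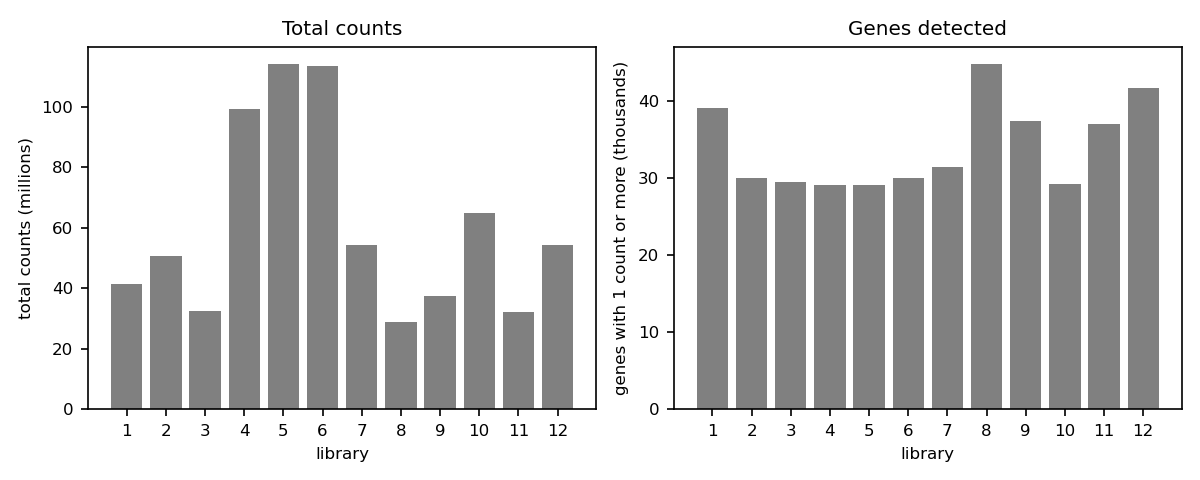
Total counts (left) and genes with at least 1 count (right), 1 bar per library, both axes scaled as labelled. Libraries 4, 5 and 6 hold at least 99503986 counts each, and libraries 1, 8, 9, 11 and 12 have at least 36958 genes with a count against at most 31450 in the other 7.

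Gene programmes that mark medulloblastoma subgroups in textbook accounts differed strongly between the xenografts, while cell division genes differed little. The sonic hedgehog list held the developmental regulators ATOH1 and EYA1, the hedgehog-binding protein HHIP, PDLIM3 and the secreted WNT antagonist SFRP1. HHIP ranged from 0.189 to 492 counts scaled to a common library size (CPM), with a median of 5.58 and an SD of 4.05 on the log2 scale (n = 12), and ATOH1 from 0 to 283 CPM (SD 4.39, n = 12). In the group 3 list, IMPG2, which encodes a protein of the photoreceptor matrix, ranged from 1.94 to 1145 CPM (SD 3.66, n = 12). In the group 4 list, EOMES, a transcription factor of the unipolar brush cell lineage, ranged from 0.0949 to 871 CPM (SD 4.80, n = 12). By contrast, the proliferation antigen MKI67 stayed between 171 and 614 CPM (SD 0.53, n = 12) and TOP2A, the topoisomerase of dividing cells, between 237 and 1028 CPM (SD 0.60, n = 12).

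Members of 12 of the 20 lists that could be tested rose and fell together more than random lists of the same size and expression. The mean pairwise Spearman correlation was 0.784 in the sonic hedgehog list (5 genes detected), 0.728 in MYC targets (12 genes), 0.622 in the group 3 list (6), 0.618 in photoreceptor genes (8), 0.596 in the hedgehog pathway (9) and 0.486 in proliferation (12). Each of these 6 lists had an adjusted p of 0.000667 in a one-sided test against 10000 random lists, which can give no raw p below 0.0001, with Benjamini-Hochberg adjustment over the 20 lists. Lower mean correlations past the threshold were 0.356 for the group 4 list (adjusted p = 0.00533), 0.309 for endothelial cells and pericytes and 0.307 for astrocytes (both 0.00475), 0.245 for the cerebellar granule lineage and 0.238 for oligodendrocytes (both 0.0173), and 0.236 for neuronal differentiation (0.0332). The threshold was not passed by the WNT subgroup list at 0.191 (adjusted p = 0.152), TGF-beta and SMAD genes at 0.125 (0.0617), the unipolar brush lineage at 0.0546 (0.267), NOTCH genes at 0.0326 (0.396), imprinted genes at -0.00419 (0.555), WNT targets at -0.0102 (0.614), the oncogenes at -0.0140 (0.825) or the 23 detected lncRNAs named in medulloblastoma work at -0.0161 (0.914). The mean of MYC targets was highest in libraries 4, 5 and 10 (1.65, 1.48 and 0.91). Those libraries also had the highest shares of ribosomal protein genes (8.65%, 9.96% and 6.73%), and whether the 2 are linked was not tested. These tests describe the 12 libraries, since genes are not independent replicates.

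Single libraries decided 5 of these calls. Neuronal differentiation lost its call without library 1 (mean correlation 0.228, adjusted p = 0.105), library 2 (0.231, 0.0607), library 3 (0.148, 0.179) or library 7 (0.178, 0.197). The granule lineage lost its call without library 7 (0.159, 0.127) and oligodendrocyte markers without library 9 (0.172, 0.0546). TGF-beta and SMAD genes passed without library 3 (0.161, 0.0290), library 4 (0.133, 0.0459), library 9 (0.153, 0.0427) or library 12 (0.165, 0.0285). The microglial list had 2 genes detected and was not tested, but without library 4 it had 3 and passed (0.571, 0.0352). Within the 7 libraries with fewer genes detected, the mean correlation was 0.821 for the sonic hedgehog list, 0.796 for MYC targets and 0.874 for the 4 photoreceptor genes detected there (adjusted p = 0.001 each, random lists). In the same 7 libraries the group 4 list at 0.222 (adjusted p = 0.0995) and oligodendrocyte markers at 0.0612 (0.377) did not pass, and TGF-beta and SMAD genes at 0.202 (0.0436) did. The other 5 libraries are too few for a value of their own.

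**Figure D2:**
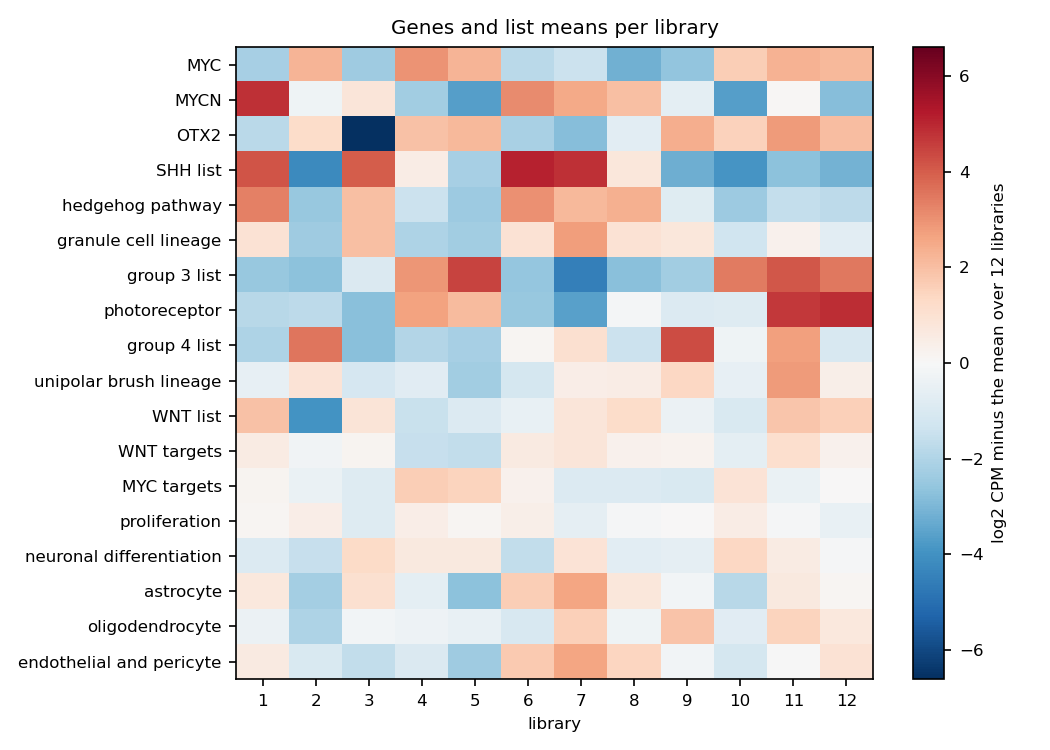
Level of MYC, MYCN, OTX2 and 15 gene lists (vertical axis) in each library (horizontal axis), as log2 CPM minus the mean over the 12 libraries, averaged over a list's detected members. The sonic hedgehog list runs from -4.21 to 5.11 and the group 3 list from -4.53 to 4.46, and the proliferation list stays between -0.85 and 0.50.

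Photoreceptor genes rose with OTX2, the homeobox gene that acts upstream of photoreceptor fate in the retina. OTX2 had a median of 443 CPM and ranged from 1.73 to 1201 CPM (SD 2.86 on the log2 scale, n = 12). The photoreceptor list mean rose with it across the 12 libraries (Pearson r = 0.710, permutation p = 0.00826; Spearman rho = 0.818, permutation p = 0.00181). This was 1 of 8 preset list pairs tested, with a Benjamini-Hochberg adjusted p of 0.0145 for rho and 0.0661 for r, and r was 0.675 (p = 0.0313) without the 2 libraries farthest from the median of OTX2. The adjusted p of rho rose above the threshold without library 1 (rho 0.764, 0.0668), library 3 (0.773, 0.0597), library 6 (0.764, 0.0638) or library 7 (0.773, 0.0556). Within the 7 libraries with fewer genes detected, where 4 photoreceptor genes were detected, rho was 0.964 (exact permutation p = 0.00278). Photoreceptor genes were low: the median CPM of the 8 detected members had a median of 0.234, under the detection minimum of 0.5 CPM. The list mean therefore rests on many values near that minimum.

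MYC targets, genes of ribosome assembly and growth such as NPM1, NCL and FBL, had a Spearman rho of 0.657 with the proliferation list (permutation p = 0.0243, adjusted 0.0972; r = 0.594, p = 0.0421, and 0.459 without the 2 farthest libraries, n = 12). The adjusted p fell under the threshold without library 2 (rho 0.736, 0.0477) or library 5 (0.764, 0.0351). MYC targets with MYCN had a rho of -0.392 (permutation p = 0.209, adjusted 0.317; r = -0.518, p = 0.0868, and -0.568 without the 2 farthest, n = 12). Neuronal differentiation with proliferation had a rho of -0.203 (permutation p = 0.530; r = -0.388, p = 0.214, and -0.0184 without the 2 farthest, n = 12). The group 4 list with the unipolar brush lineage had a rho of 0.559 (permutation p = 0.0635, adjusted 0.169; r = 0.507, p = 0.0955, and 0.673 without the 2 farthest, n = 12). The other pairs that did not pass joined astrocyte with oligodendrocyte markers (rho 0.371, permutation p = 0.238; r = 0.474, p = 0.121, and 0.221 without 2), astrocyte with microglial markers, a mean of 2 genes (0.0769, 0.817; r = 0.228, p = 0.472, and -0.0618 without 2), and microglial with vascular markers (0.462, 0.135; r = 0.520, p = 0.0846, and 0.207 without 2). Of the list pairs, 4 fell into separate clusters, in which no pooled correlation is given. They were MYC with its targets, the sonic hedgehog list with the hedgehog pathway, and the group 3 list with photoreceptor genes and with the group 4 list. Within clusters of at least 6 libraries, rho was 0.6 and 0.2 for MYC with its targets (exact permutation p = 0.242 and 0.714, n = 6 each). For the sonic hedgehog list with the hedgehog pathway it was 0.0357 (exact permutation p = 0.963, n = 7), and for the group 3 list 0.179 with photoreceptor genes (exact permutation p = 0.713, n = 7) and -0.286 with the group 4 list (exact permutation p = 0.556, n = 7). Between clusters no test was run. Libraries 1, 3, 6, 7 and 8 lay above the other 7 in both the sonic hedgehog list and the hedgehog pathway, which share HHIP. Their sonic hedgehog list means were 0.73 to 5.11, against at most 0.50 in the other 7. In the remaining clustered pairs, the means of the second list overlapped between the clusters. In the 7 libraries with fewer genes detected, MYCN with MYC targets had a rho of -0.679 (exact permutation p = 0.110) and astrocyte with oligodendrocyte markers 0.5 (exact permutation p = 0.267).

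MALAT1, a nuclear lncRNA retained in speckles, was the most abundant lncRNA in these xenografts. It had a median of 5012 CPM and ranged from 2137 to 10370 CPM (SD 0.70 on the log2 scale, n = 12). NORAD, a cytoplasmic lncRNA that binds Pumilio proteins, had a median of 332 CPM and TUG1 of 186 CPM, and both varied little (SD 0.28 and 0.32, n = 12). LINC00461, a brain lncRNA that shares exon positions with a microRNA 9 precursor, had a median of 233 CPM but ranged from 2.06 to 643 CPM (SD 2.28, n = 12). The remaining lncRNAs among the 10 with the highest medians were AC006064.5 at 784 CPM, LRRC75A-AS1 at 259, SNHG14 at 228, OIP5-AS1 at 225, AC087190.3 at 177 and FTX at 168 CPM. Each of these, as well as MALAT1, LINC00461 and TUG1, shares exon positions with other annotated genes, and the strand setting of the counting is not stated, so their levels are uncertain by the reads of those genes. All of AC006064.5 lies within exon positions of the small Cajal body RNA gene SCARNA10, and AC087190.3 lies within those of C16orf72.

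**Figure D3:**
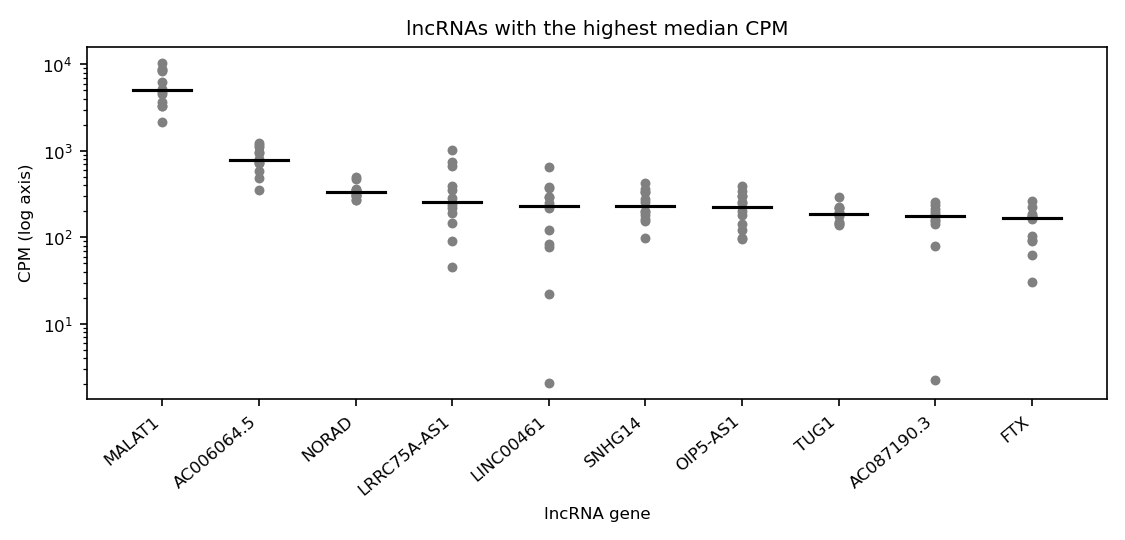
CPM (log axis) of the 10 lncRNA genes with the highest median; each point is 1 of the 12 libraries and each line the median. MALAT1 lies between 2137 and 10370 CPM, above the other 9 genes in their medians, and LINC00461 spans 2.06 to 643 CPM.

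Among lncRNAs named in medulloblastoma work, 23 of 30 reached 0.5 CPM in at least 3 libraries. MIAT ranged from 1.90 to 929 CPM (median 31.0), GAS5, the host of many small nucleolar RNAs, from 13.9 to 1126 CPM (median 101), and NEAT1, the scaffold of paraspeckles, from 3.69 to 301 CPM (median 54.3). PVT1, the neighbour of MYC, ranged from 0.314 to 275 CPM (median 3.77) and DLEU2 from 18.3 to 56.1 CPM (median 23.9). HOTAIR reached no more than 0.680 CPM and UCA1 no more than 0.266 CPM. LINC01419 was at 697 CPM in 1 library with a median of 0.143 CPM.

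lncRNA genes, which were more weakly expressed, reached 0.5 CPM in fewer xenografts than coding genes, but at a given mean level they varied less. Of 3916 lncRNA genes detected, 26.9% reached 0.5 CPM in all 12 libraries and 41.9% in 3 to 6 libraries, against 70.2% and 12.6% of 14970 coding genes. The median SD of log2 CPM was 1.20 for lncRNA genes and 2.06 for coding genes matched on mean log2 CPM, a difference of -0.87 (p = 0.0001 from 10000 draws, the smallest they can give). The difference ran from -1.01 to -0.85 when each library was left out, was -1.29 in the 7 libraries with fewer genes detected, and was -0.63 with matching on the highest log2 CPM. Without matching, the order was the opposite, with 1.20 for lncRNA and 0.88 for coding genes, because the comparison then set weakly expressed lncRNAs (median of the mean log2 CPM -0.56) against coding genes at 4.09. Both classes hold genes of low mean that were listed at 0 in 7 libraries, such as the coding gene ITPK1 and the lncRNA AL360012.1. Whether these zeros are expression or counting is not known, and their share in the SDs was not tested. Each lncRNA and gene here is a member of a class, not a replicate.

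The lncRNAs with the largest SD were at or near 0 in some libraries and reached at least 9.54 CPM in others. They were AL360012.1 (SD 4.83 on the log2 scale, n = 12), CU634019.1, AC008780.1, FP236241.1, AP000459.1, AC008780.2, AC239798.4, AC067930.1, AC110813.1 and DHRS4-AS1 (SD 3.96). AC008780.1 and AC008780.2, which lie side by side on chromosome 5, reached 65.1 and 60.4 CPM and were at 0 in 7 and 5 libraries. All of AL360012.1 lies within exon positions of the spliceosomal RNA gene RNU11, and AC239798.4, AC067930.1, AC110813.1 and DHRS4-AS1 also share exon positions with other genes, so these 5 are uncertain. The same holds for CU634019.1 and FP236241.1, listed at 0 in 7 and 5 libraries, and for AC008780.1, AC008780.2 and AP000459.1, since whether the listed zeros are expression or counting is not known. Among coding genes, the largest SDs belonged to CPLX3 (5.44, 0 to 278 CPM), a complexin of retinal ribbon synapses, and AC138811.2 (5.41). They were followed by DUSP16, the tumour antigen PRAME (5.17, 0 to 502 CPM), MAB21L2 (5.11, 0.187 to 1897 CPM), ITPK1, PLCH2, RYBP, FAM198B (4.97, 0 to 308 CPM) and CARMIL3 (4.84). CPLX3, AC138811.2, PRAME, MAB21L2 and FAM198B share exon positions with another annotated gene. DUSP16, PLCH2 and RYBP were listed at 0 in 6, 3 and 5 libraries and at no less than 10 CPM in every other library, ITPK1 and CARMIL3 were listed at 0 in 7, and whether these zeros are expression or counting is not known, so their SDs are uncertain.

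Several lncRNAs rose and fell with the developmental regulator beside them. OTX2-AS1 followed OTX2, MYCNOS followed MYCN, DLX6-AS1 followed DLX6 and EMX2OS followed EMX2 across the 12 xenografts, each with a Spearman rho above 0.9. OTX2-AS1 (ENSG00000248550.3) ranged from 0.0351 to 87.7 CPM, and MYCNOS (ENSG00000233718.7) ranged from 0 to 24.5 CPM beside MYCN (ENSG00000134323.11) at 1.95 to 704 CPM. Other members were low in most libraries. DLX6 had a median of 0.339 CPM and reached 0.5 CPM in 4 libraries. EMX2 and EMX2OS had medians of 0.627 and 1.38 CPM, and each reached 10 CPM in 1 library. CDKN2B, the partner of CDKN2B-AS1, had a median of 0.436 CPM. Relations of these genes therefore rank many values near the detection minimum. Of 16 preset lncRNA and gene pairs, 10 could be tested and 7 passed an adjusted p of 0.05 for rho, with Benjamini-Hochberg adjustment over the 10.

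OTX2-AS1 and OTX2 had r = 0.888 (permutation p = 0.00024), rho = 0.923 (permutation p = 7e-05, adjusted 0.000225), and r = 0.988 without the 2 libraries farthest from the median of the lncRNA (n = 12). MYCNOS and MYCN had r = 0.933 (permutation p = 3e-05), rho = 0.909 (permutation p = 9e-05, adjusted 0.000225), and r = 0.912 without 2 (n = 12). DLX6-AS1 and DLX6 had r = 0.924 (permutation p = 1e-05, the smallest the permutations can give), rho = 0.932 (permutation p = 5e-05, adjusted 0.000225), and r = 0.942 without 2 (n = 12). EMX2OS and EMX2 had r = 0.954 (permutation p = 1e-05), rho = 0.930 (permutation p = 5e-05, adjusted 0.000225), and r = 0.894 without 2 (n = 12). SOX2-OT and SOX2, the stem cell factor inside its intron, had r = 0.844 (permutation p = 0.00019), rho = 0.846 (permutation p = 0.00079, adjusted 0.00158), and r = 0.839 without 2 (n = 12). CRNDE and IRX5, its divergent neighbour, had r = 0.658 (permutation p = 0.0195), rho = 0.783 (permutation p = 0.00364, adjusted 0.00607), and r = 0.617 without 2 (p = 0.0530, n = 12). CDKN2B-AS1 and CDKN2B, an inhibitor of the cell cycle, had r = 0.650 (permutation p = 0.0229), rho = 0.671 (permutation p = 0.0195, adjusted 0.0279), and r = 0.295 without 2 (p = 0.409, n = 12), so that this relation rests on those 2 libraries.

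MYCNOS shares 98 bp of exon with MYCN and EMX2OS 255 bp with EMX2, on opposite strands, and because the strand setting is not stated these 2 relations are uncertain. The other 5 related pairs share no exon positions, though DLX6-AS1, CDKN2B-AS1 and SOX2-OT overlap their partner gene, and OTX2-AS1 and CRNDE lie 2704 and 1673 bp from theirs (hg38 build). CDKN2B-AS1 no longer passed without library 6 (rho 0.573, adjusted p = 0.107), library 9 (0.573, 0.0962) or library 11 (0.573, 0.0906). CRNDE without library 6, OTX2-AS1 without library 8 and SOX2-OT without library 11 fell into separate clusters and could not be tested. Within the 7 libraries with fewer genes detected, rho was 0.929 for MYCNOS (exact permutation p = 0.00675, adjusted 0.0270), 0.786 for CRNDE (exact permutation p = 0.0480, adjusted 0.0640) and 0.429 for CDKN2B-AS1 (exact permutation p = 0.354). There OTX2-AS1, SOX2-OT and EMX2OS fell into separate clusters and DLX6-AS1 was below the detection minimum, and the other 5 libraries are too few.

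Relations that did not pass were those of NEAT1 with MALAT1 (r = 0.498, permutation p = 0.0986; rho = 0.441, permutation p = 0.153, adjusted 0.191; r = 0.325 without 2, n = 12), MEG3 with DLK1 (r = 0.40, p = 0.198; rho = 0.401, p = 0.199, adjusted 0.222; r = 0.597 without 2) and TP73-AS1 with TP73 (r = -0.0405, p = 0.902; rho = -0.0595, p = 0.857; r = 0.0133 without 2). NEAT1 and MALAT1 had a rho of 0.786 in the 7 libraries with fewer genes detected (exact permutation p = 0.0480, adjusted 0.0640). MYC fell into 2 separate clusters of 6 libraries, so that PVT1 and MIR17HG were related to it only within each. There PVT1 had a rho of 0.714 (exact permutation p = 0.136) among the libraries with lower MYC and 0.0857 (exact permutation p = 0.919) among those with higher MYC, and MIR17HG -0.0857 in both (exact permutation p = 0.919, n = 6). H19 with IGF2 and KCNQ1OT1 with CDKN1C, imprinted neighbours, also fell into separate clusters. Within their larger clusters rho was 0.350 (permutation p = 0.321, n = 10) and 0.766 (permutation p = 0.0132, n = 10; r = 0.688, permutation p = 0.0258). The cluster of KCNQ1OT1 still held separate clusters of CDKN1C, listed at 0 in libraries 1 and 2 and at 1.03 CPM or more in the rest. Libraries 1 and 2 also had the lowest KCNQ1OT1 of the 10. The rho of 0.766 thus spans these clusters and is not a relation within 1 of them. Without library 3, H19 and IGF2 no longer fell into clusters and had a rho of 0.661 (permutation test, adjusted p = 0.0448). NKX2-2-AS1 and HOTAIRM1 were below the detection minimum.

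**Figure D4:**
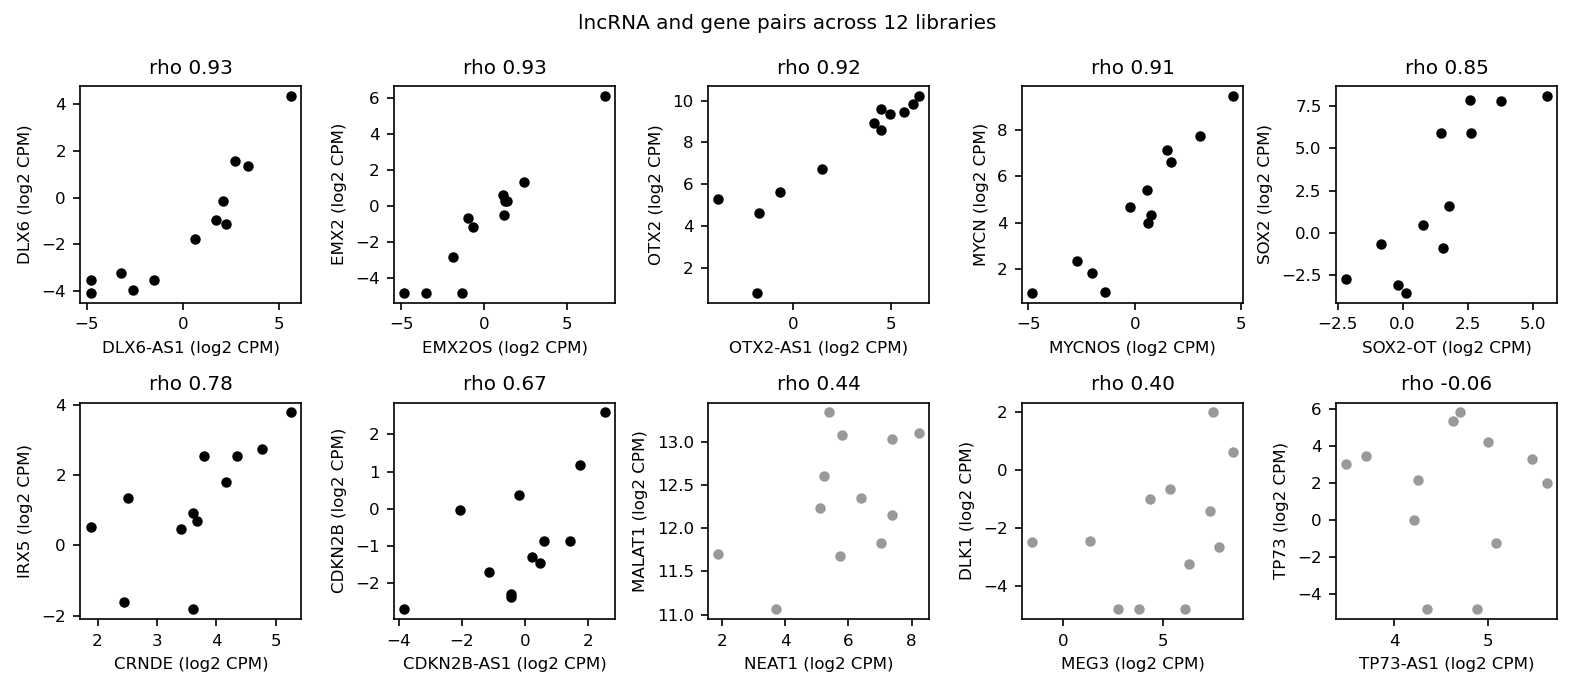
Log2 CPM of each of the 10 preset lncRNAs tested (horizontal axis) against its partner gene (vertical axis); each point is 1 of the 12 libraries, black where the adjusted p of rho is below 0.05 and grey otherwise. The 7 black panels have a rho of 0.67 to 0.93 and the 3 grey ones of -0.06 to 0.44.

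PTCH1, BOC and SMO of the hedgehog pathway had positive slopes with MYCN across the 12 xenografts, and the calls over all genes were lost without library 10 or 12. Libraries 1, 3, 6, 7 and 8, which lay highest in the hedgehog pathway list, also had the highest MYCN. They had 42.8 to 704 CPM, against at most 25.8 CPM in the other 7. Slopes with MYCN can therefore reflect a difference between these libraries and the rest, and no test within either set was run. Per unit of log2 MYCN, the hedgehog receptor PTCH1 rose by 0.40 ± 0.07 (log2 ± SE) and the co-receptor BOC by 0.99 ± 0.16 (n = 12). GABRA5, a GABA receptor subunit in the group 3 list, had a slope of -1.09 ± 0.21 but did not pass over all genes (edgeR adjusted p = 0.0511). MYCN had a median of 23.0 CPM, and 30 genes rose and 10 fell with it among 14687 tested, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (n = 12).

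The 5 coding genes with the smallest unadjusted p that rose with MYCN were FLCN, the folliculin tumour suppressor (slope 0.41 ± 0.05), LLGL1, a cell polarity gene (0.36 ± 0.05), RNF112 (0.91 ± 0.13), RASSF2 (0.88 ± 0.13) and SH3BGRL3 (0.42 ± 0.06), each with an edgeR quasi-likelihood Benjamini-Hochberg adjusted p of 0.022, a value that another rising coding gene shared. FLCN, LLGL1 and RNF112 lie on chromosome 17, between 17212212 and 19417276 (hg38), but genes that rose with MYCN were not enriched on that chromosome after adjustment (6 of 30, Fisher's exact p = 0.00689, Benjamini-Hochberg adjusted 0.165). Enrichment on a part of the chromosome was not tested. The genes that fell with MYCN included ALDH5A1, an enzyme of GABA breakdown (-0.51 ± 0.07, adjusted p = 0.022), the potassium channel gene KCNJ2 (-0.96 ± 0.15, 0.0376), RPRM (-0.79 ± 0.13, 0.0404), GNB3, a G protein subunit of cone photoreceptors (-0.92 ± 0.16, 0.0409) and DOK6 (-0.66 ± 0.12, 0.0409), by the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. LINC01694 was the 1 lncRNA past the threshold among 1565 tested (-0.65 ± 0.10, edgeR quasi-likelihood Benjamini-Hochberg adjusted p = 0.022). Of these 11 genes, FLCN shares exon positions with a gene on the same strand and LLGL1, RNF112, SH3BGRL3, ALDH5A1, KCNJ2, GNB3 and DOK6 with a gene on the opposite strand, and since the strand setting is not stated the levels of all 8 are uncertain.

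In the hedgehog pathway, PTCH1 and BOC rose over all genes tested (edgeR adjusted p = 0.0409 and 0.0404), and SMO (0.44 ± 0.09) and HHIP (0.69 ± 0.25) rose adjusted over the list alone, while SUFU (0.06 ± 0.10) did not pass. In the sonic hedgehog list 3 of 3 tested members (PDLIM3 0.99 ± 0.30, SFRP1 0.88 ± 0.21 and HHIP) rose, adjusted over the list alone, and in the group 3 list 3 of 3 (GABRA5, EYS -0.91 ± 0.30 and IMPG2 -0.81 ± 0.32) fell, adjusted over the list alone. Over all genes tested, 0 members of these 2 lists passed in the edgeR test, in which 2295 genes had an unadjusted p under 0.05, DESeq2 passed 1006 genes and limma-trend 53. Adjusted over their lists alone, the MYC targets LDHA (-0.28 ± 0.09) and TFRC (-0.26 ± 0.07), TGFBR1 (-0.19 ± 0.05) and ID1 (-0.42 ± 0.15) fell, and NHLH1 of the granule lineage (0.50 ± 0.12) rose. The pericyte gene RGS5 (0.16 ± 0.07) was the 1 member of its list tested, so its p of 0.0425 adjusted over the list alone carries no correction, and over all genes the edgeR adjusted p was 0.304. The 12 proliferation genes had slopes of -0.11 to 0.08, and 0 passed adjusted over the list alone, as in the 14 lncRNAs tested of the medulloblastoma lncRNA list and in the lists not named here, with MYC left out because its libraries fell into separate clusters. Genes low in several libraries, such as ATOH1, CRX, GLI1, GLI2 and GLI3, were below the filter on low counts and were not tested.

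Which genes passed with MYCN depended on single libraries. The count of 40 became 0 without library 10 (1793 genes at an unadjusted p under 0.05 by edgeR) and 0 without library 12 (2314 genes), 1 without library 5, 3 without library 7, 7 without library 6, 12 without library 8, 23 without library 9, 24 without library 2 and 105 without library 1. In the 7 libraries with fewer genes detected 2 genes passed, and with the detection split as a term 24 did, 17 of them among the 40. By DESeq2's Wald test 1006 genes passed. FLCN and LLGL1 passed in 9 of the 12 fits that each left out 1 library, with adjusted p up to 0.0574 and 0.0628, and GNB3 in 2 of the 12, with adjusted p up to 0.0972 (edgeR).

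**Figure D5:**
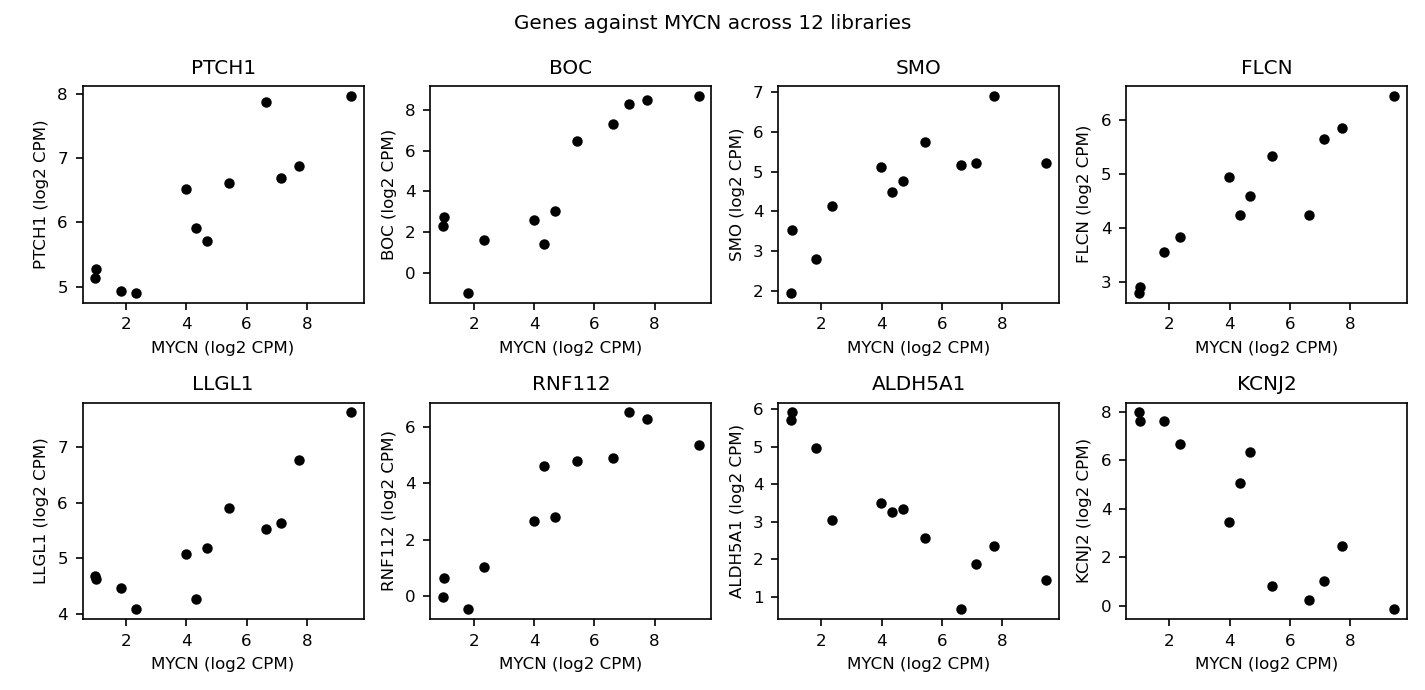
Log2 CPM of 8 genes (vertical axis) against log2 CPM of MYCN (horizontal axis); each point is 1 of the 12 libraries. The hedgehog pathway genes PTCH1, BOC and SMO and the chromosome 17 genes FLCN, LLGL1 and RNF112 have positive slopes of 0.36 to 0.99, and ALDH5A1 and KCNJ2 have slopes of -0.51 and -0.96.

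Along OTX2, no member of a subgroup list passed over all genes by edgeR, and some passed within their list. MYCN itself fell with OTX2 in the same libraries, so slopes along both are not independent. Libraries 1, 3, 6, 7 and 8, the highest in MYCN, were the lowest in OTX2. They had 1.73 to 105 CPM, against at least 391 CPM in the other 7, so slopes along OTX2 can also reflect that split. Adjusted over their lists alone, PDLIM3 (-1.37 ± 0.31), SFRP1 (-1.09 ± 0.25) and HHIP (-0.89 ± 0.38) of the sonic hedgehog list fell with OTX2, as did BOC (-1.19 ± 0.28) of the hedgehog pathway. The group 3 genes GABRA5 (1.20 ± 0.35) and IMPG2 (0.90 ± 0.25) and the MYC target LDHA (0.37 ± 0.09) rose, adjusted over the list alone, while EYS (0.20 ± 0.22) did not pass. MYCN (-0.87 ± 0.29), NHLH1 (-0.42 ± 0.11), CNTN2 (-0.44 ± 0.15) and the lncRNA NEAT1 (-0.41 ± 0.09) fell, adjusted over the list alone. Over all 14687 genes, 0 rose and 3 fell by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, while 1476 had an unadjusted p under 0.05. The 3 were the actin-binding gene PALLD (-0.41 ± 0.06), the centrosome gene PCNT (-0.39 ± 0.05) and APP, the amyloid precursor (-0.40 ± 0.06), each with an adjusted p of 0.0297, and PALLD and APP share exon positions with another gene. DESeq2's Wald test passed 593 genes, limma-trend 4 and edgeR without a filter on low counts 9. The edgeR count was 0 without library 1, 4, 5, 7, 9, 10 or 12 (1131 to 1650 genes at an unadjusted p under 0.05), 36 without library 3, 7 without library 6 and 6 without library 8, 10 with the detection split as a term and 1 in the 7 libraries with fewer genes detected. Library 3 lay far below the others in OTX2, at 1.73 CPM against at least 24.5 CPM. Of the 3 genes, 1 passed without that library. PALLD passed in 5 of the 12 fits that each left out 1 library, and PCNT and APP in 3 each (edgeR).

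No gene passed for the proliferation list or for MYC by edgeR's quasi-likelihood test. With the proliferation list, all 12 MYC targets had positive slopes (median 1.08 per unit of the list mean) and all 9 neuronal differentiation genes tested had negative ones (median -0.87), but 0 passed adjusted over the list alone. NKD1, a WNT feedback inhibitor, fell (-2.57 ± 0.68), adjusted over the list alone. Over all 14676 genes 0 passed, against 1681 at an unadjusted p under 0.05, 306 by DESeq2's Wald test, 0 by limma-trend and 1 by edgeR without library 11. For MYC, which ranged from 1.64 to 121 CPM in 2 separate clusters, no fit over all libraries was made, and its own slopes along MYCN and OTX2 are not given for the same reason. Among the 6 libraries with lower MYC 0 genes passed by edgeR (563 at an unadjusted p under 0.05, 119 by DESeq2, 0 by limma-trend), and among the 6 with higher MYC 0 passed (343, 114 by DESeq2, 0 by limma-trend).

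Markers of other brain cells ranged from listed zeros to above 10 CPM in all 12 libraries. The oligodendrocyte gene CNP was at 32.2 to 155 CPM in all 12 (median 61.2), and the astrocyte genes SLC1A2 and SLC1A3 had medians of 89.6 and 9.96 CPM. The host was a mouse, and whether mouse reads were separated is not stated, so a level of these genes need not come from tumour cells. Of 10 microglial genes, 2 reached 0.5 CPM in at least 3 libraries, too few for a test of the list, and AIF1 was listed at 0 in all 12. A listed 0 sets no upper limit on expression here, since the values are estimated counts and broadly expressed genes such as ACTN4 and RCC2, chosen after their values were seen, were also listed at 0 in 1 library. The astrocyte gene GFAP had a median of 1.47 CPM and reached 129 CPM. The oligodendrocyte gene MBP had a median of 2.70 CPM, MOG was listed at 0 in all 12, and the endothelial gene PECAM1 reached 6.60 CPM. COL1A2, a collagen gene, had a median of 1.18 CPM and reached 855 CPM. Astrocyte and vascular list means ranged from -2.72 to 2.59 and from -2.35 to 2.60 around their means over the libraries.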

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

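The alternatives that used the 9 less deep libraries, the 7 libraries with fewer genes detected, the detection split as a term, or matching on the median or highest log2 CPM were chosen after seeing the data. No called gene, list or pair changed direction under the alternatives run. Of 240 list values with 1 library left out, 230 kept their side of the threshold, 4 gained it and 6 lost it. Of 206 pair values 197 kept it, 2 gained it and 7 lost it. Of 168 values of the 14 genes named for MYCN or OTX2, 84 kept their call and 84 lost it.

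Leaving out 1 library at a time, the number of lncRNA and gene pairs past the threshold ran from 5 to 8, of list pairs from 0 to 2 and of coherent lists from 10 to 14. The number of genes related to MYCN ran from 0 (without library 10 or 12, edgeR, 1793 and 2314 genes at an unadjusted p under 0.05) to 105 (without library 1), to OTX2 from 0 (without library 1, 4, 5, 7, 9, 10 or 12) to 36 (without library 3), and to the proliferation list from 0 to 1 (without library 11). The difference in variability of lncRNAs ran from -1.01 to -0.85. For MYC, leaving out a library within the clusters of 6 was not run.

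With a detection minimum of 1 CPM in 6 libraries, 4 lncRNA pairs passed, because DLX6-AS1, EMX2OS and CDKN2B-AS1 fell below it, and 7 lists were coherent: neuronal differentiation, the granule lineage, astrocytes and vascular markers missed the threshold, and photoreceptor genes kept 1 member and could not be tested. In the 7 libraries with fewer genes detected 1 lncRNA pair passed (MYCNOS with MYCN), and OTX2-AS1, SOX2-OT and EMX2OS could not be tested there. List pairs past the threshold were 2 with library sizes without mitochondrial and the 10 most abundant genes and 0 in the 9 less deep libraries, where OTX2 with photoreceptor genes fell into separate clusters. With these library sizes neuronal differentiation had an adjusted p of 0.0527 (random lists), and in the 9 less deep libraries oligodendrocyte markers one of 0.0882. The library sizes raised the median detected gene by 0.32 on the log2 scale, and NORAD to 413 CPM and TUG1 to 232 CPM.

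Genes related to MYCN were 65 with no filter on low counts (25 of the 40 among them), 1006 by DESeq2's Wald test (40), 24 with the detection split as a term (17) and 2 in the 7 libraries with fewer genes detected (1). For OTX2 these were 9, 593, 10 and 1. For the proliferation list 3 genes passed with no filter and 306 by DESeq2's Wald test, and for MYC that test passed 119 and 114 genes in the clusters with lower and higher MYC. The cause of these differences was not tested. A listed 0 sets no limit on expression in these estimated counts.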

Other observations

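Of the tests here, the comparison of lncRNAs with their nearest genes across the genome was set up before its result was seen; every other test was chosen after its pattern was seen.

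OTX2-AS1, SOX2-OT, DLX6-AS1, CRNDE and CDKN2B-AS1 varied with a neighbouring gene with which they share no exon positions in the annotation used here. Reads of exons that overlap in that annotation therefore do not account for these 5 pairs. The submitters' annotation release is not stated, so reads shared in their counting are not excluded. SOX2-OT, DLX6-AS1 and CDKN2B-AS1 also overlap their partner gene outside exons, and reads shared there were not tested. In the 2 pairs with shared exon positions (MYCNOS with MYCN, EMX2OS with EMX2), shared reads stay open, since gene totals cannot separate the strands. Across the genome, 2202 lncRNAs and their nearest detected coding gene within 50000 bp and without shared exon positions had a median Spearman rho of 0.378, with 78.4% above 0. The highest median of 1000 shuffles of the partners was 0.028 (p = 0.001, the smallest they can give), so neighbours varied together more than lncRNAs and genes paired at random. A structure of the libraries can give shuffled pairs positive and negative correlations that cancel in a median. The test therefore cannot exclude such a structure as a cause in the preset pairs. The median was 0.324 in 1230 pairs whose genes do not overlap and 0.280 in 1210 pairs with shared exon positions, and genes are not independent replicates. A shared regulation of neighbours, or a gain or loss of their region in some tumours, may relate them, and neither was tested.

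Coding genes such as RAD17, SIRT2, ACTN4 and RYBP, named here after their values were seen, were listed at 0 in at least 1 library and at 10 CPM or more in every other. There were 14 such genes among 9228 with a median of at least 10 CPM, with 30 values at 0 spread over 11 libraries. All 91 genes with a library at 0 were tested first: 49.5% shared exon positions with another gene, against 51.6% in matched draws (one-sided p = 0.671), and the number of them at 0 per library had a Spearman rho of -0.293 with total counts (permutation p = 0.353, n = 12). The 14 genes were singled out after that test showed no excess, and 42.9% of them shared exon positions, against 50% in matched draws (one-sided p = 0.802), while the nearest gene differed by a median of -0.39 on the log2 scale between libraries at 0 and the others (one-sided p = 0.880). At the lowest level these 14 genes had in other libraries, each library at 0 would hold at least 345 counts. This follows from their choice at 10 CPM or more, which is 289 counts in the least deep library, and is not a separate test. At those levels depth alone would not give a 0 in the 14, while depth stays open for the other genes of the 91. Loss of reads to overlapping genes or to the nearest gene stays open, and no biological explanation was tested.

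Of the 30 genes that rose with MYCN, 6 lie on the short arm of chromosome 17 (FLCN, LLGL1, RNF112, ZNF286A, ZNF287 and ATPAF2, the last 3 named after their values were seen) against 1.75 expected on the whole chromosome (Fisher's exact p = 0.00689, adjusted 0.165 over the chromosomes). That test covered all 857 genes tested on both arms, and enrichment on the short arm alone was not tested. The mean of the other 218 genes tested on that arm had a rho of 0.161 with MYCN (permutation p = 0.622, n = 12) and an r of 0.227 (p = 0.479) that became 0.630 without the 2 farthest libraries (permutation p = 0.0496). Its rho was 0.5 in the 7 libraries with fewer genes detected (exact permutation p = 0.267), and 69.7% of these genes had positive slopes against 26.1% on the rest of the chromosome. A test of opposite shifts of the 2 arms was added after that one missed: the arm's mean minus that of 632 genes on the rest of the chromosome had a rho of 0.601 (permutation p = 0.0429, adjusted over the 2 tests 0.0858; r = 0.636, p = 0.0298, and 0.793 without the 2 libraries farthest from the median of MYCN) and 0.607 in the 7 libraries with fewer genes detected (exact permutation p = 0.167). Genes not called were also grouped in windows of 10000000 bp, ranked by median slope with MYCN from 1 (highest) to 256. On chromosome 17, the windows starting at 1 and 10000001 ranked 9 and 1 (median slopes 0.073 and 0.112, rho 0.210 and 0.273). Those starting at 20000001, 30000001 and 40000001 ranked 217, 232 and 205. Those from 50000001, 60000001, 70000001 and 80000001 ranked 254, 255, 252 and 256 (slopes -0.105 to -0.080). The ranks were not tested. Copy number changes of the arms that accompany MYCN level may relate these genes. Neither of the 2 correlation tests passed after adjustment, so this stays open.

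For MYCN, 1 of 101 orders of its values, the real one included, gave as many genes as the 40 found by edgeR, and the highest of the others gave 1. Such a count was thus rare among orders of all 12 libraries. The shuffles were not run with a library left out. With 0 genes without library 10 or 12 by edgeR (1793 and 2314 genes at an unadjusted p under 0.05), 1 without library 5 and 3 without library 7, chance is not firmly excluded for MYCN. For OTX2, 5 of 101 orders gave at least the 3 found and the highest of the others gave 10, so that the share lies just under 0.05 while some orders gave more genes than the real one. With 0 genes without library 1, 4, 5, 7, 9, 10 or 12 by edgeR (1131 to 1650 genes at an unadjusted p under 0.05), chance is not firmly excluded for OTX2. For the proliferation list, edgeR found 0 genes (1681 at an unadjusted p under 0.05, 306 by DESeq2's Wald test, 0 by limma-trend), which all 101 orders must reach, so this comparison says nothing about chance. Its highest other orders gave 140 and 36 genes, as a structure of the libraries can, and the cause was not tested. The last 60 of the 100 shuffled orders were added after the first 40 had been seen.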
